A study of Mus musculus with 22 samples.

How the data were processed

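The values are read counts per gene. Per the labels the authors deposited 1 table of raw HTSeq counts for 20 libraries of the Tet1 cross and 1 table for 2 wild-type libraries of the MF1 cross, and the whole numbers in both tables fit that unit. Per the submitters' processing notes the reads had been trimmed with Trimmomatic, aligned to the mm9 mouse genome with TopHat2 2.0.2 and Bowtie 0.12.8, and counted with HTSeq 0.5.3p9. The strand setting and the treatment of reads that fit several places were not stated, so counts of overlapping genes on opposite strands and of near-identical gene copies, such as Tuba3a with Tuba3b or members of the Ifitm family, could hold reads of one another.

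The table of the Tet1 cross held 37991 Ensembl genes and that of the MF1 cross 37620, all of which were in the first table as well. Symbols were assigned by Ensembl identifier, and 32919 and 32897 of these genes received one. Gene type and chromosome class came from the GENCODE annotation of a later mouse genome build than the authors used, so no positions are given. List members without a match were Lhx8, Snrpn, Rian, Mirg, Kcnq1ot1, Peg13, Hbb-b1 and Hbb-b2.

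Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and drawn with Python 3.11.15 and matplotlib 3.10.9. Genes with enough counts (edgeR's filterByExpr, minimum count 10 and minimum total 15) were kept, which left 17567 genes for the 20 libraries of the Tet1 cross. Libraries were scaled by TMM, and 1 coefficient was fitted for each of the 10 groups with edgeR's robust quasi-likelihood method, which gave a common biological coefficient of variation of 0.46 and 10 residual degrees of freedom. The comparison of the MF1 cross with E10.5 Tet1-WT was a separate fit of 4 libraries and 15500 genes, with a coefficient of 0.78. A gene counted as called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and every p for a gene is the adjusted p of edgeR's quasi-likelihood test unless an unadjusted one is named. The average comparison weighted the 5 stage and sex groups equally. A test of the difference took the Tet1-KO effect in males minus that in females.

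Levels are in CPM (counts over the TMM-scaled library total) given as mean ± SD over the libraries of a group. Changes are fitted log2 ratios with their standard errors (SE), first group against second, with an edgeR prior count of 0.125. Where every library of a group held 0 counts of a gene, the fold is a lower bound computed with 3 counts per library in that group. Such bounds cover counting error only, because amplified reads without molecular identifiers are not independent molecules.

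The 19 gene lists, the comparisons, the alternatives and the naming rule below were fixed before the data were examined. Each list was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. The p values of the 19 lists were adjusted together within each comparison by Benjamini-Hochberg. Counts described as adjusted over the list alone repeat the gene adjustment among the members of the list. The lists were methylation-sensitive germline genes, piRNA and transposon defence, meiotic prophase, pluripotency, early PGC, male germ cell differentiation, female germ cell signalling and oocyte, DNA methylation machinery, imprinted genes, mitotic cell cycle, stress and dissociation, supporting cells of testis, supporting cells of ovary, steroidogenic cells, gonadal and mesonephric mesenchyme, erythroid cells, endothelial and blood cells, hindgut epithelium, and a check of sex labels. Some genes stood in more than 1 list, and the lists of other cell types were included because sorted fractions can hold RNA of neighbouring cells.

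Genes were named by a fixed rule. It took Tet1 in every library. In each comparison it took the 6 largest called rises and the 6 largest called falls among genes whose libraries did not overlap between the groups and whose higher group mean was at least 5 CPM, without pseudogenes and genes that carry only a clone name. From each list it took up to 4 called members with the smallest p, or up to 2 with the highest level where none was called. In the Tet1-KO comparisons it also took 15 fixed germ cell genes, among them Dazl, Ddx4, Mael, Sycp1, Sycp3, Stra8, Nanos2, Pou5f1, Sox2, Dppa3 and Xist. The text gives the values of a part of the genes so named.

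Counts were simulated in 1 run with 1 spread per gene, shared by all groups. Levels and spreads were edgeR's own estimates, which may favour edgeR. In the simulated counts edgeR recovered between 10% and 19% of genes changed 2-fold in a comparison of 2 libraries with 2. It recovered between 47% and 66% of genes changed 4-fold, with 0% to 8.6% false calls. DESeq2 gave 15.7% to 26.4% false calls there and limma's voom with sample quality weights 10% to 21.1%, so edgeR supplied the reported calls. In the data the groups differed in spread. Their common biological coefficient of variation ran from 0.2 in E12.5 female Tet1-KO to 0.83 in the libraries labelled Tet1-KO at E10.5. The simulated rates therefore need not hold for groups of unequal spread. Replicate numbers are those of the deposited column names, except in the sexed Tet1-KO groups. Both column names of each such group are alike, so its libraries are counted in column order. The pairing of equal replicate numbers across groups was tested by 15 correlations of replicate differences, which lay between -0.032 and 0.048, so libraries were treated as unpaired.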

Results

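RNA was sequenced from sorted primordial germ cells (PGCs), the embryonic precursors of eggs and sperm, of mouse embryos with or without a working Tet1 gene, which encodes an enzyme that oxidises methylated cytosine in DNA. Embryos were taken at E10.5, when the sexes were not separated, and as females and males at E12.5 and E14.5. The Tet1 cross gave 20 libraries in 10 groups, Tet1-KO and Tet1-WT at each stage and sex, and a second cross with MF1 females and males carrying a Pou5f1 reporter gave 2 wild-type libraries at E10.5. Each group held 2 libraries, each made from pooled RNA of 2 to 6 embryos per the labels, so every mean ± SD is over n = 2. Total counts per library (M for mega) of the Tet1 cross ranged from 9.62 M to 25.9 M. At E10.5 they were 16.5 and 18.38 M in Tet1-WT and 14.88 and 17.19 M in Tet1-KO. At E12.5 they were 16.32 and 18.55 M in female Tet1-WT, 24.88 and 14.96 M in female Tet1-KO, 15.3 and 15.26 M in male Tet1-WT, and 12.33 and 15.66 M in male Tet1-KO. At E14.5 they were 21.1 and 9.62 M in female Tet1-WT, 14.09 and 20.6 M in female Tet1-KO, 17.25 and 25.9 M in male Tet1-WT, and 16.61 and 18.06 M in male Tet1-KO. The MF1 libraries held 59.42 and 66.92 M. Between 15147 and 20012 genes had at least 1 count, and correlations of log CPM between replicates ran from 0.834 in the MF1 cross to 0.978.

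Tet1 itself came first, as the gene the cross was made to remove. At E12.5 its level was 179 and 226 CPM in the female Tet1-WT libraries against 53.1 and 68.9 CPM in Tet1-KO, and 178 and 309 against 79.3 and 84.5 CPM in males. At E14.5 it was 35.2 and 49.2 CPM against 20.97 and 25.8 CPM in females, and 218 and 155 against 99.5 and 79.9 CPM in males. At E10.5 the Tet1-WT libraries held 134 and 76.8 CPM and the Tet1-KO libraries 44.5 and 102 CPM, so Tet1-KO replicate 2 lay above Tet1-WT replicate 2. For that stage the groups are therefore called libraries labelled Tet1-KO and Tet1-WT, and every direction drawn there or in the average of all groups rests on those labels. The summed early PGC genes were lower in Tet1-WT at E10.5 (2764 and 2001 CPM) than in the libraries labelled Tet1-KO (8837 and 5736 CPM). The Tet1 levels of that stage may therefore not stand against equal amounts of germ cell RNA. The MF1 libraries held 286 and 108 CPM of Tet1. Tet1 fell in E12.5 females by 1.73 on the log2 scale (SE 0.37, adjusted p = 0.0303), a call lost without Tet1-WT replicate 2 (adjusted p = 0.202), Tet1-KO replicate 1 (0.257) or Tet1-KO replicate 2 (0.229). In the other stage and sex groups the log2 difference was between -1.57 and -0.52 and was not called, with adjusted p = 0.388 at E10.5, 0.0553 in E12.5 males, 0.204 in E14.5 females and 0.292 in E14.5 males. The tables count reads over the whole gene, so they do not show whether the RNA that remained could make the protein.

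**Figure D1:**
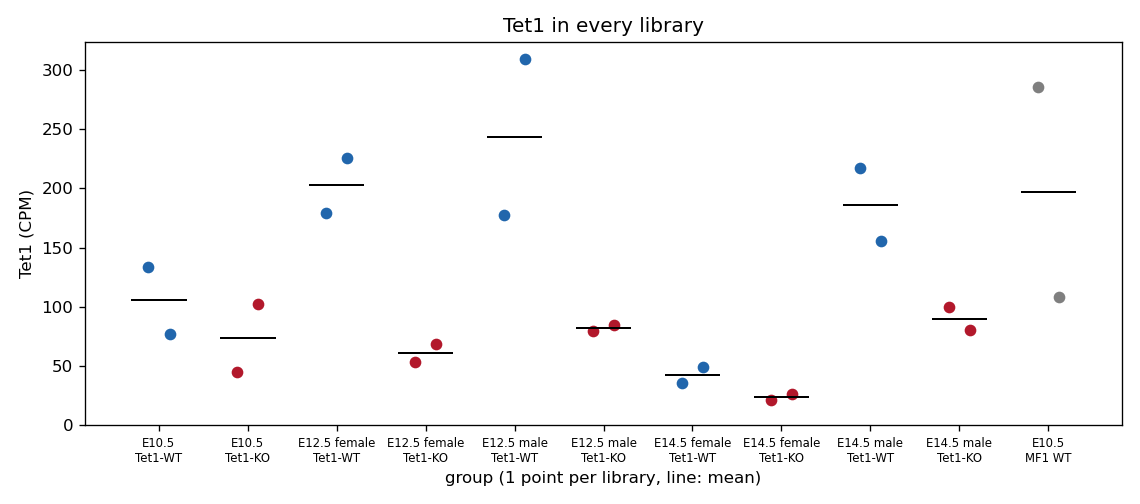
Tet1 level in CPM (linear axis from 0) for each library of the 11 groups, with a line at each group mean. At E10.5 the library labelled Tet1-KO replicate 2, at 102 CPM, lies above Tet1-WT replicate 2, at 76.8 CPM.

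The first comparison asked which genes differed at E10.5 between libraries labelled Tet1-KO and Tet1-WT. Early germ cell and pluripotency genes were higher and imprinted genes lower in the libraries labelled Tet1-KO. Dppa3, a maternal factor expressed in early germ cells, stood at 2670 ± 946 CPM against 788 ± 79.3 CPM (log2 1.76, SE 0.26, adjusted p = 0.00158). Sox2, a pluripotency transcription factor, stood at 90.8 ± 12.7 against 22.9 ± 9.94 CPM (log2 1.99, SE 0.3, adjusted p = 0.00174). H19, an imprinted noncoding RNA, stood at 196 against 576 CPM (log2 -1.55, SE 0.31, adjusted p = 0.00717). Of 25 measured pluripotency genes 17 rose and 0 fell (21 and 2 adjusted over the list alone), Pou5f1, Sall4 and Dppa2 among them, with a median log2 of 1.52 (adjusted p = 2.72e-22, camera). Of 14 early PGC genes 11 rose and 0 fell (13 and 0 adjusted over the list alone), with a median log2 of 1.61 (adjusted p = 8.41e-21). Without Tet1-WT replicate 2, these counts were 10 and 6. Both list calls held with an estimated correlation, at adjusted p = 0.00979 and 0.029. Of 36 imprinted genes 7 fell and 1 rose (12 and 1 adjusted over the list alone), Asb4 by 2.44 on the log2 scale (adjusted p = 0.00128), and the list call held (adjusted p = 5.43e-05, and 0.0477 with an estimated correlation). The imprinted falls numbered 3 without Tet1-WT replicate 1, Tet1-WT replicate 2 or Tet1-KO replicate 1.

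Germline genes that gain expression as DNA methylation is lost moved in both directions at E10.5. Of 28 such genes 11 rose and 3 fell (14 and 6 adjusted over the list alone), with a median log2 of 0.92 (adjusted p = 5.43e-05, but adjusted p = 0.174 with an estimated correlation). Of 35 meiotic prophase genes 10 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 4.01e-05, but 0.14 with an estimated correlation). Stag3, a subunit of the meiotic cohesin that holds sister chromatids together, stood at 63.6 ± 5.61 against 22 ± 3.41 CPM (log2 1.53, SE 0.2, adjusted p = 0.00109). Hormad1, which binds meiotic chromosome axes, stood at 0.747 CPM in libraries labelled Tet1-KO against 5.64 CPM (log2 -3.02, adjusted p = 0.00754). Dazl, an RNA-binding protein of germ cells, stood at 18.1 ± 5.33 against 11.7 ± 10.1 CPM (adjusted p = 0.384), and Ddx4, a germ cell RNA helicase, at 58 against 26.9 CPM (adjusted p = 0.0637). Of 26 piRNA pathway genes, which silence transposons, 6 rose and 0 fell (11 and 3 adjusted over the list alone; adjusted p = 0.000255, but 0.174 with an estimated correlation). The germline rises numbered 6 without Tet1-WT replicate 1 and 7 without Tet1-KO replicate 1. The meiotic rises numbered 6 without Tet1-WT replicate 1, and without Tet1-KO replicate 1 the meiotic list lost its call (adjusted p = 0.0919).

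Markers of gonadal and mesonephric mesenchyme, a tissue next to the germ cells, moved the opposite way at E10.5. The summed level of the 15 markers was 1671.5 and 1971.5 CPM in Tet1-WT and 382.6 and 846 CPM in the libraries labelled Tet1-KO. Of these markers 2 fell and 0 rose (5 and 0 adjusted over the list alone; adjusted p = 5.43e-05, and 0.0477 with an estimated correlation), with 0 falling without Tet1-WT replicate 2, 1 without Tet1-KO replicate 1 and 5 without Tet1-KO replicate 2. Of 12 endothelial and blood cell genes 2 fell (3 adjusted over the list alone; adjusted p = 0.0405, but 0.196 with an estimated correlation), Esam by at least 27.9-fold and Tek by at least 20.2-fold, both endothelial surface proteins, of which Tek lost its call without any 1 of the 4 libraries (adjusted p from 0.0624 to 0.152). Emcn, an endothelial surface protein outside that list, fell by at least 53.1-fold. The list call was lost without Tet1-KO replicate 1 (adjusted p = 0.136), Tet1-KO replicate 2 (0.0689) or Tet1-WT replicate 1 (0.0995). None of the other lists was called. Their adjusted p was 0.39 for male germ cell differentiation (2 rose), 0.0899 for female germ cell signalling and oocyte (4 rose), 0.402 for DNA methylation machinery (Gadd45a rose and Uhrf1 fell), 0.39 for mitotic cell cycle (1 rose, 1 fell) and 0.635 for stress and dissociation (2 rose, 1 fell). It was 0.39 for supporting cells of testis (1 fell), 0.0899 for those of ovary, 0.55 for steroidogenic cells (1 rose), 0.542 for both erythroid cells and hindgut epithelium, and 0.42 for the check of sex labels. The median of male germ cell differentiation genes was 0.01 but their mean -0.21, the median of mitotic genes was 0.19 but their mean -0.02, and stress genes had a median of -0.38 although their ranks leaned higher.

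In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1547 of 17567 genes at E10.5, 721 higher and 826 lower in the libraries labelled Tet1-KO. The largest changes included Slain1, a microtubule-binding protein, at 7.41 ± 0.595 against 0.469 ± 0.0242 CPM (log2 3.96, SE 0.57, adjusted p = 0.00128), Map3k15, a kinase (log2 3.78, adjusted p = 0.0147), and Zfp128, a zinc finger gene that was at least 75.6-fold lower. The count was 972 without Tet1-WT replicate 1 and 470 without Tet1-WT replicate 2. It was 2819 with DESeq2, 2578 without the filter on low counts, 246 with limma's voom, 1 with the mesenchyme level as a covariate (a setting added after the data were seen) and 0 in a fit of these 4 libraries alone, where 2 libraries per group set the spread.

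**Figure D2:**
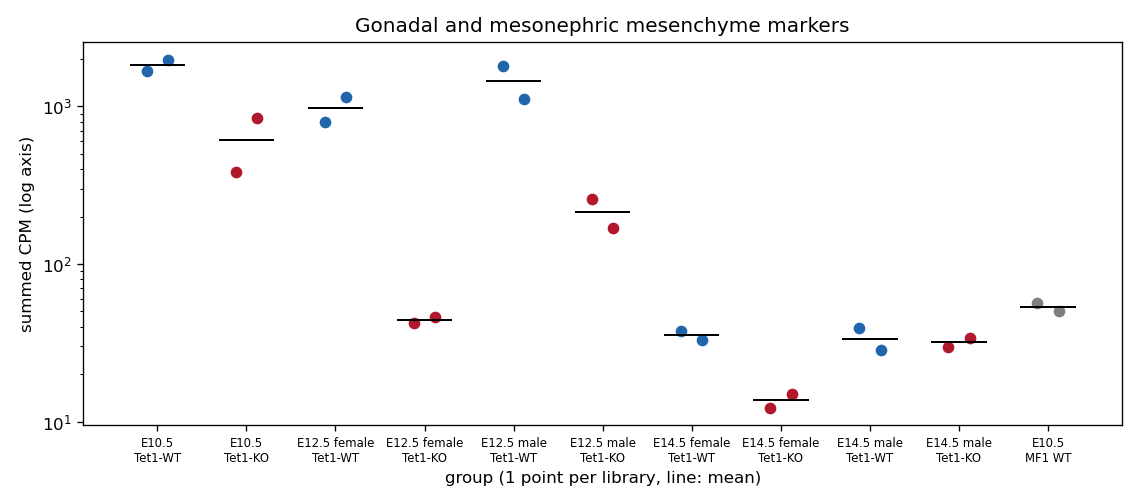
Summed level of 15 markers of gonadal and mesonephric mesenchyme in CPM (log axis) for each library of the 11 groups, with a line at each group mean. At E12.5 the female Tet1-KO libraries sit at 42.1 and 46 CPM and the female Tet1-WT libraries at 794.1 and 1148.4 CPM.

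At E12.5 in females, the Tet1-KO comparison asked what differed soon after sex determination. Most called genes were lower in Tet1-KO, and imprinted genes and mesenchyme markers were prominent among them. H19 stood at 18.9 ± 1.2 CPM in Tet1-KO against 117 ± 11.8 CPM (log2 -2.63, SE 0.32, adjusted p = 0.000671), and Cdkn1c, an imprinted inhibitor of cell division, at 22.4 ± 1.71 against 177 ± 68.5 CPM (log2 -2.98, adjusted p = 0.000826). Nr2f2, a nuclear receptor of mesenchyme, stood at 13.6 ± 0.198 against 331 ± 149 CPM (log2 -4.61, SE 0.45, adjusted p = 0.000248), and Col1a1, a fibrillar collagen, at 4.34 ± 1.04 against 148 ± 53.8 CPM (log2 -5.11, SE 0.54, adjusted p = 0.000307). Of 36 imprinted genes 11 fell and 0 rose (13 and 0 adjusted over the list alone), with a median log2 of -1.1 (adjusted p = 1.12e-17, and 0.000765 with an estimated correlation). Of 15 mesenchyme markers 8 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -4.19 (adjusted p = 6.87e-29, and 0.000269 with an estimated correlation), and their summed level was 42.1 and 46 CPM in Tet1-KO against 794.1 and 1148.4 CPM. The falls in these lists numbered 6 imprinted genes and 5 markers without Tet1-WT replicate 2, and 3 of each without Tet1-KO replicate 1 or replicate 2.

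Germ cell genes of E12.5 females held few calls. Of the pluripotency genes 1 rose and 1 fell (2 and 1 adjusted over the list alone; adjusted p = 7.72e-05, but 0.233 with an estimated correlation). The rise was Pou5f1, a pluripotency transcription factor, at 254 ± 61.6 against 106 ± 10.9 CPM (log2 1.26, SE 0.29, adjusted p = 0.0429), a call lost without any 1 of the 4 libraries (adjusted p = 0.0674 and 0.355 without Tet1-WT replicates 1 and 2, and 0.111 and 0.5 without Tet1-KO replicates 1 and 2). No meiotic prophase gene was called among 35 (0 rose and 3 fell adjusted over the list alone; adjusted p = 0.000675, but 0.233 with an estimated correlation). Stra8, a gene needed to start meiosis, stood at 2.5 ± 2.14 CPM in Tet1-KO (log2 -2.84, SE 0.68, adjusted p = 0.0558), and Sycp3, of the synaptonemal complex that joins paired chromosomes, at 38.7 against 68 CPM (adjusted p = 0.116). Of the methylation-sensitive germline genes 0 were called (1 rose and 5 fell adjusted over the list alone; adjusted p = 0.00261, but 0.365 with an estimated correlation), with Dazl at 782 ± 120 against 1620 ± 638 CPM. Zfp57, which protects methylation at imprinted regions, fell by 3.72 on the log2 scale (adjusted p = 0.029), a call lost without Tet1-WT replicate 2 (0.239), Tet1-KO replicate 1 (0.262) or Tet1-KO replicate 2 (0.281). Zfp57 also stood lower with the mesenchyme markers at E10.5 (19 CPM in libraries labelled Tet1-KO against 98.4 CPM). In E12.5 males it stood at 8.9 against 39.7 CPM, so its fall cannot be assigned to germ cells. Xist, the RNA that silences an X chromosome, stood at 2.34 ± 0.0847 against 25.2 ± 7.33 CPM (log2 -3.43, adjusted p = 0.0654). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 227 genes were called, 25 higher and 202 lower. The count was 648 and 71 without Tet1-WT replicates 1 and 2 and 45 and 36 without Tet1-KO replicates 1 and 2, and 0 with the mesenchyme level as a covariate. It was 785 with DESeq2, 799 with limma's voom, 943 without the filter and 494 in a fit of these 4 libraries alone.

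At E12.5 in males, called genes were again mostly lower in Tet1-KO. Grb10, an imprinted adaptor protein that restrains growth, stood at 18.4 ± 5.75 CPM in Tet1-KO against 436 ± 167 CPM (log2 -4.57, SE 0.56, adjusted p = 0.00314, but 0.117 without Tet1-KO replicate 2). H19 stood at 32.1 ± 11.3 against 151 ± 72.6 CPM (log2 -2.24, adjusted p = 0.00631, but 0.0995 without Tet1-WT replicate 1 and 0.118 without Tet1-KO replicate 2). Nr2f2 stood at 63.6 ± 9.78 against 391 ± 93.1 CPM (log2 -2.62, adjusted p = 0.00666, but 0.101 without Tet1-WT replicate 1, 0.061 without Tet1-KO replicate 1 and 0.152 without Tet1-KO replicate 2). Of 36 imprinted genes 10 fell and 0 rose (13 and 0 adjusted over the list alone; median log2 -1.09, or -0.97 with genes at 0 set to their bounds; adjusted p = 3.87e-11, and 0.00518 with an estimated correlation). Of 15 mesenchyme markers 5 fell and 0 rose (9 and 0 adjusted over the list alone; median -2.62, adjusted p = 6.88e-12, and 0.00518 with an estimated correlation), and their summed level was 259.4 and 169.6 CPM in Tet1-KO against 1790 and 1116.4 CPM. The imprinted falls numbered 1 without Tet1-WT replicate 1, 4 without Tet1-KO replicate 1 and 0 without Tet1-KO replicate 2, and the marker falls numbered 0 without any of these 3. Pluripotency genes held 1 rise and 0 falls (9 and 1 adjusted over the list alone; adjusted p = 1.58e-08, but 0.0585 with an estimated correlation), and early PGC genes 0 of either (7 and 0 adjusted over the list alone; adjusted p = 5.68e-07, but 0.183 with an estimated correlation). Germline, piRNA and meiotic lists were not called (adjusted p = 0.358, 0.92 and 0.983) and held 1 called member, the meiotic gene Gm4969, lower at 0.0667 against 2.08 CPM (adjusted p = 0.0271, but from 0.194 to 0.297 without Tet1-WT replicate 1 or either Tet1-KO replicate), and Dazl stood at 999 against 1230 CPM. Supporting cells of testis (adjusted p = 0.0023, but 0.0585 with an estimated correlation) and stress genes (adjusted p = 0.00329, but 0.0833 with an estimated correlation) held 0 and 1 called falls. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 186 genes were called, 21 higher and 165 lower. The count was 4 without Tet1-WT replicate 1, 28 without Tet1-KO replicate 1 and 1 without Tet1-KO replicate 2, and 0 with the mesenchyme level as a covariate. It was 836 with DESeq2, 1785 with limma's voom, 901 without the filter and 1312 in a fit of these 4 libraries alone.

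At E14.5 in females, germ cells enter meiotic prophase, and the comparison asked how Tet1-KO cells stood in that change. Meiotic genes were lower and early germ cell genes higher in Tet1-KO. Sycp3 stood at 393 ± 141 CPM in Tet1-KO against 1310 ± 206 CPM (log2 -1.74, SE 0.24, adjusted p = 0.00186), and Sycp1, which bridges the axes of the synaptonemal complex, at 289 ± 88.2 against 1030 ± 136 CPM (log2 -1.84, SE 0.35, adjusted p = 0.00725). Gdf3, a growth factor of pluripotent cells, stood at 60.5 ± 13.4 against 12.2 ± 6.91 CPM (log2 2.34, SE 0.32, adjusted p = 0.00186), and Tfap2c, a transcription factor of PGC specification, at 57.6 ± 15.6 against 9.18 ± 3.37 CPM (log2 2.67, SE 0.41, adjusted p = 0.00263). The calls of Sycp3 and Gdf3 stood without any 1 of the 4 libraries. Sycp1 lost its call without Tet1-WT replicate 1 (adjusted p = 0.0904) or Tet1-KO replicate 2 (0.116), and Tfap2c without Tet1-WT replicate 1 (0.0677). Of 35 meiotic prophase genes 15 fell and 0 rose (19 and 0 adjusted over the list alone), with a median log2 of -1.58 (adjusted p = 2.93e-15, and 0.0125 with an estimated correlation). Of 28 methylation-sensitive germline genes 12 fell and 0 rose (17 and 1 adjusted over the list alone; median -1.32, adjusted p = 2.11e-12, and 0.0356 with an estimated correlation). Of 25 pluripotency genes 12 rose and 0 fell (16 and 0 adjusted over the list alone; median 1.27, adjusted p = 1.05e-16, and 0.0125 with an estimated correlation), and of 14 early PGC genes 10 rose and 0 fell (14 and 0; median 1.36, adjusted p = 1.91e-19, and 0.0234 with an estimated correlation). Without Tet1-WT replicate 1 the called members of these 4 lists numbered 1, 1, 1 and 0, and without Tet1-KO replicate 2 they numbered 1, 1, 4 and 2. Without Tet1-WT replicate 2 the meiotic and germline falls numbered 8 and 7. Each of the 4 lists kept its direction and its call without any 1 of these libraries.

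**Figure D3:**
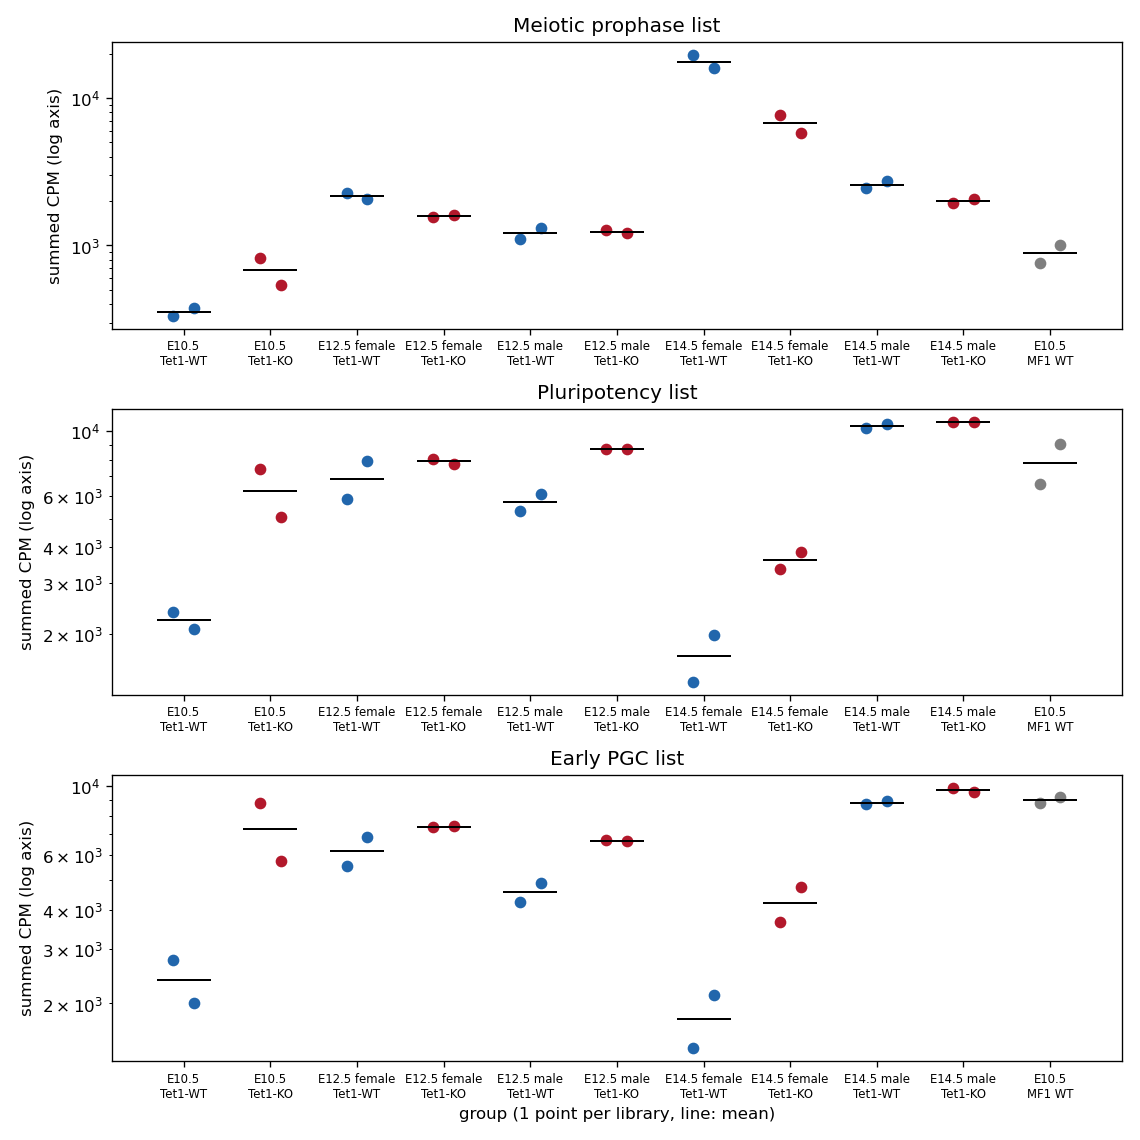
Summed level of the genes of 3 lists, meiotic prophase, pluripotency and early PGC, in CPM (log axis) for each library of the 11 groups, with a line at each group mean. In E14.5 females the meiotic sum is 7667 and 5816 CPM in Tet1-KO and 19457.2 and 15894.9 CPM in Tet1-WT.

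Mitotic cell cycle genes of E14.5 females split, with 7 rises and 3 falls among 28 (11 and 3 adjusted over the list alone; adjusted p = 0.000854, but 0.443 with an estimated correlation). Plk1, a kinase of mitosis, stood at 140 against 45.2 CPM (log2 1.63, adjusted p = 0.00263, but 0.0677 without Tet1-WT replicate 1). The mitotic rises numbered 0 without Tet1-WT replicate 1 and 1 without Tet1-KO replicate 2. Imprinted genes held 4 rises and 0 falls (7 and 3 adjusted over the list alone; adjusted p = 0.656), with a median of 0.02 but a mean of -0.57. Phlda2, an imprinted growth restrainer, stood at 493 ± 15 CPM in Tet1-KO (log2 2.29, adjusted p = 0.0137, but 0.205 without Tet1-WT replicate 1 and 0.0783 without Tet1-KO replicate 2). The imprinted rises numbered 0 without either of those libraries and 2 without Tet1-WT replicate 2. Of the mesenchyme markers 2 fell (3 adjusted over the list alone; adjusted p = 0.00498, but 0.192 with an estimated correlation), at summed levels of 12.3 and 15.1 CPM in Tet1-KO against 37.4 and 33.1 CPM. These falls numbered 0 without Tet1-WT replicate 1 or Tet1-KO replicate 2 and 4 without Tet1-KO replicate 1. Of the piRNA genes 1 fell (6 fell and 1 rose adjusted over the list alone; adjusted p = 0.013, but 0.435 with an estimated correlation). Mael, a piRNA factor, stood at 120 ± 33.5 against 512 ± 91.2 CPM (log2 -2.1, adjusted p = 0.0582), Stra8 at 387 against 670 CPM (adjusted p = 0.484) and Dazl at 1670 against 3490 CPM (adjusted p = 0.14). The largest rises held Epha4, an ephrin receptor, at 13.5 ± 3.76 against 1.37 ± 0.306 CPM (log2 3.34, SE 0.39, adjusted p = 0.00137). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 1168 genes were called, 590 higher and 578 lower. The count was 60 and 683 without Tet1-WT replicates 1 and 2, the second of which was the smallest library, and 130 without Tet1-KO replicate 2. It was 2176 with DESeq2, 1857 without the filter, 2019 with limma's voom, 537 in a fit of these 4 libraries alone and 71 with the mesenchyme level as a covariate.

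At E14.5 in males, germ cells stop dividing, and few genes were called between Tet1-KO and Tet1-WT, in a comparison that recovered 16% of simulated 2-fold and 48% of 4-fold changes. Gna14, a G protein subunit, stood at 27.2 ± 12 CPM in Tet1-KO against 4.73 ± 2.05 CPM (log2 2.54, SE 0.33, adjusted p = 0.00619, but 0.0682 without Tet1-WT replicate 2 and 0.0921 without Tet1-KO replicate 1). Afap1, an actin-binding protein, stood at 75 ± 6.85 against 24.5 ± 1.56 CPM (log2 1.61, SE 0.21, adjusted p = 0.00619, but 0.0623 and 0.105 without the same libraries). No member of the 19 lists was called. Of the methylation-sensitive germline genes 0 rose and 11 fell adjusted over the list alone (median log2 -0.73, adjusted p = 6.01e-09, but 0.28 with an estimated correlation). For piRNA genes these counts were 0 and 4 (adjusted p = 6.4e-05) and for meiotic prophase genes 0 and 3 (adjusted p = 0.000148), both at adjusted p = 0.28 with an estimated correlation. Mael stood at 74.4 ± 9.18 against 408 ± 173 CPM (adjusted p = 0.158), Sycp3 at 73.6 ± 1.62 against 132 ± 34 CPM (adjusted p = 0.185), and Nanos2, a gene of male germ cell fate, at 53 against 97.1 CPM. Pluripotency and early PGC lists were not called (adjusted p = 0.657 and 0.612), with Dppa3 at 6280 against 6120 CPM, and the mesenchyme markers summed to 29.6 and 34.1 CPM in Tet1-KO against 39.1 and 28.3 CPM (adjusted p = 0.796). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 18 genes were called, 14 higher and 4 lower, with 1815 at an unadjusted p under 0.05. The count was 37 and 3 without Tet1-WT replicates 1 and 2, and 0 and 6 without Tet1-KO replicates 1 and 2. It was 368 with DESeq2, 112 with limma's voom, 468 without the filter and 0 in a fit of these 4 libraries alone.

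Averaged over the 5 stage and sex groups, which include the E10.5 libraries labelled Tet1-KO, Tet1 fell by 1.15 on the log2 scale (SE 0.16, adjusted p = 0.00038). Early germ cell and pluripotency genes rose, with Pou5f1 up by 1.02 (SE 0.13, adjusted p = 0.000167) and Dppa3 by 0.72 (adjusted p = 0.000857). Of the pluripotency genes 19 rose and 1 fell (22 and 1 adjusted over the list alone; adjusted p = 1.78e-25, and 0.00295 with an estimated correlation), and of the early PGC genes 13 rose and 0 fell (14 and 0; adjusted p = 1.78e-25, and 0.0078 with an estimated correlation). At E10.5 and E12.5 the Tet1-WT libraries held more mesenchyme marker RNA. Part of the rises may therefore come from a lower share of germ cell RNA there, which the average cannot separate. In E14.5 males, where marker levels were alike, neither list was called. In E14.5 females, where markers were low in both groups, both lists were called. Imprinted genes held 13 falls and 1 rise (15 and 1 adjusted over the list alone; adjusted p = 1.24e-09, and 0.00622 with an estimated correlation), with H19 down by 1.4 (SE 0.14, adjusted p = 6.16e-05). The E14.5 groups did not share this fall. Their imprinted median was 0.02 in females, with 4 called rises and 0 falls, and -0.04 in males, with 0 calls. Mesenchyme markers held 9 falls and 0 rises (10 and 0; adjusted p = 5.01e-15, and 0.00295 with an estimated correlation). Methylation-sensitive germline genes held 11 falls and 1 rise (13 and 2; adjusted p = 0.000409, but 0.329 with an estimated correlation), with Mael down by 1.59 (adjusted p = 0.00285) and Hormad1 by 1.31 (adjusted p = 0.000665). Dazl (log2 -0.48, adjusted p = 0.0938) was not called. Of the DNA methylation genes 4 fell, Tet1 itself among them, and 1 rose (4 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.319), with Uhrf1, which recruits maintenance methylation, down by 0.79 (adjusted p = 0.000936). Uhrf1 stood lower together with the mesenchyme markers, at 116 against 312 CPM at E10.5. At E12.5 it stood at 48.9 against 96.8 CPM in females and 56.4 against 126 CPM in males. At E14.5 it stood at 168 against 194 CPM in females and 90.6 against 103 CPM in males. The fall of Uhrf1 therefore cannot be assigned to germ cells. For the average edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 2446 genes, 1212 higher and 1234 lower. The count was 1584 without E12.5 male Tet1-WT replicate 1, 1618 without E12.5 female Tet1-KO replicate 2, and 0 with the mesenchyme level as a covariate.

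**Figure D4:**
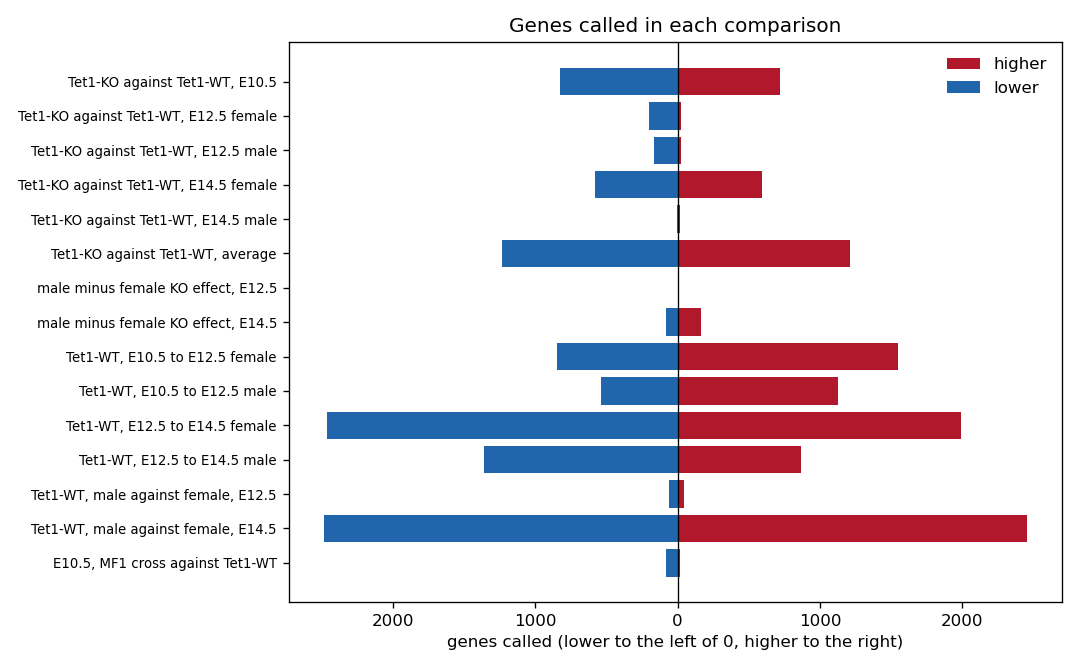
Number of genes called higher (bars to the right) and lower (bars to the left) in each of the 15 comparisons at an adjusted p under 0.05. The Tet1-KO comparisons range from 18 calls in E14.5 males to 1547 at E10.5 among single groups.

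Whether the Tet1-KO effect differed between the sexes was tested directly. At E12.5 edgeR called 0 genes for the difference, with 1007 at an unadjusted p under 0.05, and DESeq2 called 31 and limma's voom 0. The meiotic prophase list leaned higher in males than in females there (median log2 difference 0.65, adjusted p = 0.0125, but 0.714 with an estimated correlation), as did the mesenchyme markers (1.61, adjusted p = 2.16e-06, but 0.0744 with an estimated correlation). The meiotic call was lost without female Tet1-WT replicate 1 (adjusted p = 0.429), male Tet1-KO replicate 1 (0.13) or male Tet1-WT replicate 1 (0.0675). At E14.5 edgeR called 251 genes, 167 with a higher and 84 with a lower value in males, and the median over all genes was 0.11. Pluripotency genes held 3 lower and 0 higher values (13 and 0 adjusted over the list alone; adjusted p = 2.76e-11, but 0.0927 with an estimated correlation), with Gdf3 at -2.03 and Dppa2 at -2.11. Early PGC genes held 3 and 0 (11 and 0; adjusted p = 3.04e-12, but 0.131 with an estimated correlation), and meiotic genes 2 higher and 0 lower values (6 and 0; adjusted p = 0.000144, but 0.195 with an estimated correlation), Stag3 at 1.25 and Msh5 at 2.97, a factor of meiotic crossing over. Without female Tet1-WT replicate 1 or female Tet1-KO replicate 2, these 3 lists held 0 called genes. The E14.5 count was 8 without female Tet1-WT replicate 1, 166 without replicate 2 and 34 without female Tet1-KO replicate 2. It was 106 without male Tet1-WT replicate 1, and 43 and 47 without male Tet1-KO replicates 1 and 2. DESeq2 gave 1093 genes, limma's voom 555, a fit without the filter 862, a fit of the E14.5 libraries alone 44 and the mesenchyme covariate 20.

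A planned test of shared calls at E14.5 found 5 genes called in the same direction in females and males. Of the 590 female and 14 male rises 4 were shared against 0.47 with independent calls (Fisher's exact test, p = 0.000964), namely Gna14, Klhl13, Ldhb and Pls3, of which the last 3 were named after their values were seen. Of the falls 1 was shared against 0.13 (Fisher's exact test, p above 0.05), and 0 genes moved in opposite directions. The shared count was 0 without female Tet1-WT replicate 1, 9 without female Tet1-KO replicate 1, 2 without female Tet1-KO replicate 2, and 14, 0, 0 and 2 without the male Tet1-WT replicates 1 and 2 and Tet1-KO replicates 1 and 2. It was 100 with DESeq2, 40 with limma's voom and 149 without the filter. At E12.5, where the test was not planned, 93 falls were shared by females (202) and males (165) against 1.9 with independent calls (Fisher's exact test, p = 2.43e-144, although genes are not independent replicates), 1 rise was shared, and 0 genes moved in opposite directions. A second planned test asked whether genes that rose or fell from E10.5 to E12.5 in Tet1-WT shifted in Tet1-KO at E14.5, where no library is shared. In females the 849 genes that had fallen had a median log2 of 0.11 in Tet1-KO (camera p = 0.00388, but p = 0.199 with an estimated correlation). The 1547 that had risen had a median of -0.04, where the ranks leaned the other way, and in males the 1124 risen genes had a median of 0.12 and the 536 fallen genes 0.07. Camera called none of these 3 shifts at 0.05.

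In Tet1-WT, the change from E10.5 to E12.5 gave the course against which Tet1-KO was compared. Germline genes rose in both sexes, from E10.5 libraries that may have held less germ cell RNA. Smc1b, a meiotic cohesin subunit, stood at 458 ± 4.4 CPM in E12.5 females against 8.69 ± 4.22 CPM at E10.5 (log2 5.72, SE 0.31, adjusted p = 3.36e-08), and Tex19.1, a methylation-sensitive germline gene, at 420 ± 0.49 against 39.9 ± 3.93 CPM (log2 3.39, adjusted p = 4.33e-08). Of the 28 methylation-sensitive germline genes 26 rose and 0 fell in each sex (27 in females and 26 in males adjusted over the list alone; adjusted p = 5.34e-84 and 6.96e-87, and 5.68e-05 and 5.98e-05 with an estimated correlation). Meiotic prophase genes held 25 rises in females and 17 in males (28 and 23 adjusted over the list alone; adjusted p = 1.69e-37 and 1.14e-23), and piRNA genes 20 and 17. Pluripotency genes rose as well, 14 and 11 of 25, and 1 fell in each sex (17 and 13 rose and 1 fell adjusted over the list alone; adjusted p = 1.12e-13 and 1.84e-12, and 0.0106 and 0.0136 with an estimated correlation). Dppa3 stood at 2950 CPM in females and 2340 CPM in males against 788 CPM, while the E10.5 libraries of the MF1 cross held 3260 ± 957 CPM, a level no lower than at E12.5 and not tested against it. Male germ cell differentiation genes held 7 rises in males (9 adjusted over the list alone; adjusted p = 4.82e-05), with Lefty2, a Nodal inhibitor, at 177 ± 14.8 against 3.14 ± 1.23 CPM (log2 5.81), and 3 rises without either E10.5 or E12.5 Tet1-WT replicate 2. Of the imprinted genes 13 fell and 3 rose in females, and 11 fell and 1 rose in males (14 and 4, and 15 and 1 adjusted over the list alone; adjusted p = 7.09e-07 and 1.69e-10), with Peg3 lower in both and Usp29 higher in males (log2 3.1, adjusted p = 0.000683). The E10.5 Tet1-WT libraries also held mesenchyme marker RNA. Imprinted genes leaned lower in the MF1 libraries of E10.5 too (median log2 -2.04 against Tet1-WT). The imprinted falls to E12.5 therefore cannot be assigned to germ cells. The male imprinted falls numbered 7 without E10.5 replicate 2 and 4 without E12.5 replicate 2. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 2396 genes were called in females (1547 higher, 849 lower) and 1660 in males (1124 higher, 536 lower). The female count was 1480 and 1269 without E10.5 replicates 1 and 2 and 1388 without E12.5 replicate 2. The male count was 998, 772, 1089 and 483 without E10.5 replicates 1 and 2 and E12.5 replicates 1 and 2.

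Markers of other cell types moved both ways over the same step in Tet1-WT. Prrx1, a mesenchyme marker, stood at 7.06 CPM in E12.5 females and 8.31 CPM in males against 94.3 CPM at E10.5 (log2 -3.74 and -3.5, adjusted p = 0.000726 and 0.00154), and kept its call without any 1 library. Col3a1 fell in females (log2 -1.48, adjusted p = 0.0372), a call lost without any 1 of the 4 libraries. The mesenchyme list was called lower in females (adjusted p = 0.0153, but 0.187 with an estimated correlation, and 0.142 without E12.5 replicate 1) and not in males (0.0988). The embryonic globin Hbb-bh1 fell in both sexes (log2 -9.41 and -7.56, adjusted p = 0.00516 and 0.0131) and Hba-x in males (log2 -5.98, adjusted p = 0.0209), with E10.5 levels of 197 ± 241 and 256 ± 313 CPM. Without E10.5 replicate 2 none of these globin falls was called (adjusted p = 0.0509, 0.149 and 0.243). The epithelial keratins Krt8 (log2 -2.67 and -2.52, adjusted p = 0.0151 and 0.0254) and Krt18 (log2 -1.9 and -2.03, adjusted p = 0.0171 and 0.016) fell in both sexes, calls lost without E10.5 replicate 1 and without at least 1 E12.5 library. In males the testis supporting cell genes Defb19, Ptgds and Amh rose from 0 counts by at least 18.6-fold, 43.4-fold and 8.15-fold (adjusted p = 0.00185, 0.00882 and 0.048), of which Defb19 kept its call without any 1 library, Ptgds lost it without either E10.5 library and Amh without any 1 of the 4. In females 3 genes of that list fell, with Sox9 at 6.76 ± 1.07 against 38.3 ± 1.05 CPM (adjusted p = 0.00942, but 0.0662 and 0.055 without E12.5 replicates 1 and 2). The mesenchyme marker Dcn rose in males (log2 2.4, adjusted p = 0.0417), a call lost without any 1 of the 4 libraries. In females Scarb1, of the steroidogenic cell list, rose (log2 1.09, adjusted p = 0.000417) and kept its call without any 1 library, while Cx3cr1, of the blood cell list (log2 6.58, adjusted p = 0.0248), lost it without 3 of the 4. Scarb1 was the 1 called member of its list, of which 2 of 6 measured genes were higher. The list had a median log2 of -0.91 (-0.26 with genes at 0 set to their bounds) and was not called. The rise of Scarb1 therefore does not show more RNA of steroidogenic cells.

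From E12.5 to E14.5 in Tet1-WT the sexes took separate courses. In females meiotic genes rose and pluripotency genes fell, with Sycp3 at 1310 ± 206 CPM against 68 CPM (log2 4.27, SE 0.26, adjusted p = 6.94e-07), Stra8 at 670 ± 135 CPM at E14.5 (log2 5.14, adjusted p = 8.37e-05) and Dppa3 at 688 against 2950 CPM (log2 -2.1, adjusted p = 3.78e-05). Of 35 meiotic genes 30 rose and 0 fell (32 and 0 adjusted over the list alone; adjusted p = 9.4e-30), and of 25 pluripotency genes 21 fell and 0 rose (21 and 0 adjusted over the list alone; adjusted p = 3.88e-20). Tet1 fell in females, from 203 ± 33 to 42.2 ± 9.9 CPM (log2 -2.27, SE 0.38, adjusted p = 0.000385). In males piRNA genes rose, 20 of 26 (24 adjusted over the list alone; adjusted p = 4.14e-20), with Piwil4, an Argonaute protein of the piRNA pathway, at 110 against 5.33 CPM (log2 4.37, adjusted p = 0.000757). Nanos2 stood at 97.1 ± 39.3 CPM in E14.5 males against 0.188 CPM (log2 8.98, adjusted p = 0.00151). Mesenchyme markers fell in both sexes, 13 of 15 in females and 12 in males (13 and 12 adjusted over the list alone; adjusted p = 5.06e-10 and 5.02e-16), and imprinted genes held 17 falls in each (19 and 23 adjusted over the list alone; adjusted p = 9.17e-07 and 5.28e-12). All of these list calls held with an estimated correlation, at adjusted p from 0.00117 to 0.0142. The imprinted falls ran beside those of the mesenchyme markers, so they cannot be assigned to germ cells. The male piRNA rises numbered 8 and 11 without E12.5 replicates 1 and 2 and 9 without E14.5 replicate 2, and the male imprinted falls 11 without E12.5 replicate 1. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 4446 genes were called in females (1987 higher, 2459 lower) and 2227 in males (865 higher, 1362 lower). The female count was 2456 without E14.5 replicate 1, and the male count 772 and 1276 without E12.5 replicates 1 and 2 and 869 without E14.5 replicate 2. With the mesenchyme level as a covariate these counts were 1 and 0.

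Males and females of Tet1-WT were compared at each stage. At E12.5 the Y-linked Ddx3y was at least 460-fold higher in males, and Phlda2 stood at 5.85 ± 0.202 CPM against 340 ± 128 CPM in females (log2 -5.86, adjusted p = 0.000232). Of the meiotic genes 3 were lower in males and 0 higher (13 and 0 adjusted over the list alone; adjusted p = 2.43e-12, and 0.0119 with an estimated correlation). Of the female germ cell signalling genes 3 were lower (6 adjusted over the list alone; adjusted p = 4.94e-10, and 0.00219 with an estimated correlation). Without male replicate 1 the called genes of these lists numbered 2 and 1, and without male replicate 2 they numbered 1 and 0. Genes of supporting cells of testis held 1 higher value (6 adjusted over the list alone; adjusted p = 2.15e-09), Cst9, at 21.2 against 0.0295 CPM. At E14.5 meiotic genes were lower in males, 28 of 35 (31 adjusted over the list alone; adjusted p = 1.06e-21), with Sycp3 at 132 against 1310 CPM (log2 -3.32, adjusted p = 4.7e-07). Pluripotency genes were higher, 18 of 25 (18 adjusted over the list alone; adjusted p = 4.89e-17), as were male germ cell differentiation genes, 12 of 14 (13 adjusted over the list alone; adjusted p = 3.33e-11). Utf1, a chromatin factor of pluripotent cells, stood at 476 ± 29.2 against 32.5 ± 2.79 CPM (log2 3.87, adjusted p = 6.61e-07), and Tet1 at 186 ± 44.1 against 42.2 ± 9.9 CPM (log2 2.15, adjusted p = 0.000526). Between the sexes edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 43 genes higher and 58 lower in males at E12.5 and 4937 at E14.5 (2452 higher, 2485 lower). The E12.5 count was 374 and 44 without female replicates 1 and 2 and 23 and 27 without male replicates 1 and 2, 753 with DESeq2 and 583 without the filter. The E14.5 count was 2866 without female replicate 1.

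The last comparison set the MF1 cross beside Tet1-WT at E10.5, where cross, RNA kit, labelled range of cell numbers and count table differed together. Mesenchyme markers were lower in the MF1 libraries, with Col3a1, a collagen, at 3.86 ± 0.695 CPM against 325 ± 57.6 CPM (log2 -6.4, adjusted p = 0.0351), and their summed level was 56.5 and 50.3 CPM. Of 15 markers 5 were lower (13 adjusted over the list alone; adjusted p = 2.36e-24, but 0.15 with an estimated correlation), and of 36 imprinted genes 6 were lower (19 lower and 1 higher adjusted over the list alone; adjusted p = 6.78e-15, but 0.214 with an estimated correlation). Igf2, an imprinted growth factor, stood at 20.6 ± 2.51 against 511 ± 62.1 CPM (log2 -4.63, adjusted p = 0.0351). Pluripotency genes held 0 calls (19 higher and 2 lower adjusted over the list alone; adjusted p = 3.33e-13, but 0.214 with an estimated correlation), and early PGC genes 0 (12 higher; adjusted p = 4.82e-12, but 0.248 with an estimated correlation), with Dppa3 at 3260 against 792 CPM (adjusted p = 0.0775). The level of Pou5f1 is not given because the reporter of this cross carries Pou5f1 sequence, but the pluripotency and early PGC lists tested here include the gene. Methylation-sensitive germline, piRNA and meiotic prophase lists also leaned higher in the MF1 libraries, with median log2 of 1.7, 1.44 and 1.14. They held 0 calls (8, 3 and 2 higher adjusted over the list alone). Their adjusted p was 5.75e-08, 2.36e-05 and 0.000283 (camera), but 0.26, 0.248 and 0.274 with an estimated correlation. Between the crosses edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 94 of 15500 genes, 14 higher and 80 lower. The count was 51 and 25 without Tet1-WT replicates 1 and 2, and 4761 and 5290 without MF1 replicates 1 and 2. The imprinted calls numbered 2 without either Tet1-WT replicate, and 22 and 24 without MF1 replicates 1 and 2, where the markers numbered 13 and 15.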

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

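Every test of an explanation below was chosen after the pattern it addresses had been seen, and for the MF1 marker level, dilution, male cells and the Xist ratio the prediction was also written after the tested values had been seen. Each group held 2 libraries, too few to ask whether 1 library lay far from the rest, so what raised the results in the next paragraph was a tested difference between the male and the female Tet1-KO effect, given as males minus females on the log2 scale. The patterns of mesenchyme genes and of Xist weighed after it come from the Tet1-KO comparisons themselves.

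At E12.5 the difference was called for the meiotic prophase list, with a median of 0.65, and for the mesenchyme markers, with a median of 1.61, but neither call held with an estimated correlation (adjusted p = 0.714 and 0.0744). The meiotic call was also lost without female Tet1-WT replicate 1, male Tet1-WT replicate 1 or male Tet1-KO replicate 1 (adjusted p = 0.429, 0.0675 and 0.13). At E14.5 it was called for 251 genes. Among named genes the positive differences held Myrf at 7.09, Dab2 at 5.71 and Agbl2 at 5.57, and the negative ones Snai1 at -6.7, Mep1b at -6.38, Adamts14 at -5.62, Lck at -4.53 and Lgals9 at -4.21. Rnf128 (8.43), with 0 counts in both male Tet1-WT libraries, Nid1 (7.63), Adh1 (7.51) and Csf1r (10.84), with 0 in both female Tet1-KO libraries, and Prom1 (-9.02), with 0 in both male Tet1-KO libraries, were called too, but their fitted values depend on the prior count and give no size or rank. Among list members the meiotic genes Stag3 and Msh5 stood at 1.25 and 2.97, the pluripotency genes Dppa2, Utf1 and Gdf3 at -2.11, -2.08 and -2.03, and the early PGC genes Nanos3, Cxcr4 and Tfap2c at -2.17, -2.69 and -2.38. Cdc20, which drives the exit from mitosis, stood at -1.74. The list medians at E14.5 were 0.95 for meiotic prophase, -1.15 for pluripotency, -1.33 for early PGC, -0.81 for male germ cell differentiation, -0.24 for mitotic cell cycle and 1.91 for mesenchyme markers (1.51 with genes at 0 set to their bounds). None of these 6 list calls held with an estimated correlation (adjusted p = 0.195, 0.0927, 0.131, 0.195, 0.703 and 0.195 in this order). The call of Prom1 stood without any 1 of the 8 E14.5 libraries, while the 251 genes became 8 without female Tet1-WT replicate 1 and 34 without female Tet1-KO replicate 2.

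In E14.5 females early germ cell genes were higher and meiotic genes lower in Tet1-KO. Dilution by RNA of somatic cells would lower both groups alike, but their medians lay 2.94 apart on the log2 scale, which argues against it as the whole cause. Male germ cells in the female Tet1-KO libraries would bring Y-linked RNA, but Eif2s3y had 0 counts in both libraries, which allows a share of up to 0.0722% against the 17.3% needed. A slower passage of Tet1-KO germ cells through the change from E12.5 to E14.5 stays open. The Tet1-KO effect and that change correlated across 17567 genes with r = -0.35 or -0.3, by the Tet1-WT library used on each side. Spearman's rho was -0.43 and -0.38, and genes are not independent replicates. In males the same correlations were r = -0.11 and -0.2 (rho -0.08 and -0.23). The weaker female value sat at the limit set before, so a slower passage cannot be told apart from other differences between these libraries. The E12.5 Tet1-WT libraries where this change starts also held mesenchyme markers that fell by E14.5. A direct effect of Tet1 loss on meiotic genes is consistent with the same values, and while 15 called meiotic genes became 1 without Tet1-WT replicate 1 or Tet1-KO replicate 2, the list medians kept their call at -1.37 and -1.28 against -1.58.

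Mesenchyme genes were lower in Tet1-KO at E12.5 and in the libraries labelled Tet1-KO at E10.5. The MF1 libraries, from embryos with a working Tet1 gene, held at most 56.5 CPM of the 15 markers. This argues against loss of Tet1 in germ cells as the cause of low marker levels in general. Cross, RNA kit and labelled range of cell numbers differed too, however. RNA of somatic cells in the Tet1-WT libraries, where sorting should have removed such cells, may explain the pattern: 80 genes lower in the MF1 cross than in E10.5 Tet1-WT had a median log2 of -2.79 in E12.5 female Tet1-KO (quartiles -3.68 and -1.95) and of -2.18 in males (quartiles -2.65 and -1.74), with 79 of 80 lower in each. Abundant markers such as Nr2f2, Col3a1 and Col1a1 fell with the rest at E12.5. Imprinted genes such as H19 and Igf2, which mesenchyme also expresses, moved with the markers, so their falls cannot be assigned to germ cells, and an effect of Tet1 loss on the surrounding tissue or on the sort stays open and untested.

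Xist was lower at E12.5 in female Tet1-KO and at E10.5 in the libraries labelled Tet1-KO, without being called at either stage. The average Tet1-KO comparison called it (log2 -2.78, adjusted p = 0.029), a call lost without E12.5 male Tet1-WT replicate 2, and its size depends on the prior count because Xist had 0 counts in E12.5 male Tet1-KO. If RNA of somatic cells in the Tet1-WT libraries carried it, Xist should have fallen about as far as the mesenchyme markers, and the ratio of Xist to these markers differed between the groups by no more than 2.05-fold (1.4-fold at E10.5), which is consistent with that source. At E10.5 the pools were unsexed, and the Y-linked Eif2s3y stood at 38.8 ± 14.4 CPM in Tet1-WT and 39.6 ± 23.6 CPM in libraries labelled Tet1-KO. The ratio at that stage therefore cannot exclude an unequal share of females in the pools. A different activity of the X chromosome cannot be told apart here, because X-linked genes stood -0.11 from autosomal genes at E12.5 in females (407 X-linked genes) and -0.08 in males, where no inactive X is present.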

How the results depend on the processing

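The mesenchyme level as a covariate was chosen after the data were seen; every other alternative was fixed before. With DESeq2's size factors in edgeR (RLE), the count of called genes between the sexes at E12.5 changed most in proportion, to 110, and 6 results for named genes and 2 for lists changed sign, all without a call. With RLE 9 results for named genes and 2 for lists lost a call, and 1 and 2 gained one. Named genes lost 12 calls and gained 42 with DESeq2, and lost 74 and gained 31 with limma's voom. With DESeq2 the counts were 2819 at E10.5, 785 and 836 in E12.5 females and males, 2176 and 368 in E14.5 females and males, 31 and 1093 for the difference between sexes at E12.5 and E14.5, 2574 for males from E10.5 to E12.5, 753 between the sexes at E12.5, 2469 for the MF1 cross and 100 shared at E14.5. With limma's voom, run with sample quality weights here and on the simulated data, they were 246, 799, 1785, 2019 and 112 for these 5 Tet1-KO comparisons, 555 for the E14.5 difference, 2607 and 3374 for males from E10.5 to E12.5 and on to E14.5, 191 between the sexes at E12.5, 202 for the MF1 cross and 40 shared. Without the filter on low counts they were 2578, 943, 901, 1857 and 468, then 111 and 862 for both differences, 583 between the sexes at E12.5, 1370 for the MF1 cross and 149 shared. Fits of only the compared libraries gave 0, 494, 1312, 537 and 0, then 44 for the E14.5 difference, 1507 for females from E10.5 to E12.5 and 48 between the sexes at E12.5. The simulated data took 1 spread per gene for all groups from edgeR's own estimates, which may favour edgeR. They put the share of false calls of DESeq2 and voom above that of edgeR. Otherwise the cause was not tested. With the covariate the counts were 1, 0, 0 and 71 for the first 4 Tet1-KO comparisons, 0 for their average, 20 for the E14.5 difference, 649 and 775 from E10.5 to E12.5 in females and males, and 1 and 0 from E12.5 to E14.5. Its largest difference between group means was 6.8 against a spread of 0.39 within groups, so it removed much of any difference between groups by construction and cannot separate the marker level from the groups.

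Leaving out 1 library, with the lone library of the group assumed to vary like the other groups, gave counts from 470 to 2021 at E10.5, 36 to 648 and 1 to 166 in E12.5 females and males, 60 to 1370 and 0 to 37 in E14.5 females and males, 1584 to 3133 for the average, and 0 to 23 and 8 to 369 for the differences between sexes. It gave 1269 to 1911 and 483 to 1089 from E10.5 to E12.5 in females and males, 2456 to 3818 and 772 to 1882 from E12.5 to E14.5, 23 to 374 and 2866 to 3824 between the sexes, 25 to 5290 for the MF1 cross and 0 to 14 shared. The cause was not tested. For the genes that changed from E10.5 to E12.5 in Tet1-WT, the median in Tet1-KO at E14.5 ran from -0.1 to -0.02 for female rises, 0.03 to 0.18 for female falls, 0.03 to 0.16 for male rises and 0 to 0.12 for male falls. DESeq2 gave -0.05 for female rises, with ranks then leaning lower without a call, and 0.02 for female falls, which lost their call. The call of male rises was gained without the filter (0.15) and with voom (0.18), and with voom the female falls had a median of -0.06 although their ranks leaned higher.

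Among results for single genes with 1 library left out, 4208 kept their direction and call status, 737 lost a call, 52 gained one, 190 changed sign without a call and 5 went the other way under a call or, for Esam, to 0 from a call. Without E10.5 Tet1-KO replicate 1, Rec8 stood at -10.26 at E10.5 and -1.92 in the average, against highest values of 1.68 and 0.5 without replicate 2. Without E14.5 female Tet1-WT replicate 1, Esam stood at 0 between the sexes, against -6.17 without replicate 2. Without MF1 replicate 2, Top2a and Fst stood at 0.49 and -9.77 in the MF1 comparison, against -0.75 and 1.19 without replicate 1. The values of Rec8 at -10.26 and -1.92, of Fst at -9.77 and of Esam rest on groups left with 0 counts, so they depend on the prior count and give no size: E10.5 Tet1-KO replicate 2 and MF1 replicate 1 held 0 counts of Rec8 and Fst, and both male libraries 0 of Esam. The mitotic list in E14.5 male Tet1-KO stood at -0.23 without Tet1-WT replicate 2 and 0.32 without replicate 1, and the erythroid list in the MF1 comparison at 2.22 without Tet1-WT replicate 2 and -1.57 without replicate 1. The cause was not tested. Fits with the replicate number as a block gave 1766 genes at E10.5, 393 for the MF1 cross, 2415 and 1657 from E10.5 to E12.5 in females and males, 4440 and 2200 from E12.5 to E14.5, and 107 and 4932 between the sexes, and 11 results for named genes lost a call and 3 gained one. No paired analysis was possible for the sexed Tet1-KO groups, their average, the differences between sexes, the shared calls and the E14.5 test of developmental genes. The column names of the Tet1-KO libraries in those groups are alike and do not tell the replicates apart. At these depths and with 2 libraries per group, simulated 2-fold changes were mostly missed (10% to 19% recovered), so a gene without a call cannot be read as unchanged, and a gene at 0 counts is known only to lie under 3 counts per library.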

Other observations

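Both tests below were chosen after the results they address had been seen, and for the early germ cell genes the prediction was also written after the tested values had been seen.

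At E10.5 the summed level of the early PGC genes was 2764.5 and 2001.2 CPM in the Tet1-WT libraries, 8837 and 5735.7 CPM in the libraries labelled Tet1-KO, and 8828 and 9180 CPM in the MF1 wild-type libraries, whose fit put Tet1-WT at 2808 and 1985 CPM. One hypothesis is that the E10.5 Tet1-WT libraries held less germ cell RNA than the others. It needs early germ cell genes to be higher in wild-type libraries of the other cross too, and their sum was 3.76-fold higher in the MF1 cross than in Tet1-WT, against 3.06-fold in the libraries labelled Tet1-KO (3.72-fold and 3.04-fold without Pou5f1, a check added after the result was seen because the MF1 reporter carries its sequence). The cross, the RNA kit and the range of cell numbers in the labels differed as well. This test therefore could not separate a lower share of germ cells from a difference between crosses. The rise of such genes from E10.5 to E12.5 in Tet1-WT carries the same doubt. So do the rises of germline, piRNA and meiotic genes in the libraries labelled Tet1-KO at E10.5, because these lists also leaned higher in the MF1 cross. For the same reason the rises of these lists from E10.5 to E12.5 in Tet1-WT may be too large. The germline list rose by a median log2 of 3.99 in females and 3.67 in males over that step, against 1.7 in the MF1 comparison.

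Erythroid genes, which no Tet1-KO comparison called, varied within groups at E10.5, with summed levels of 135.6 and 1849.6 CPM in Tet1-WT and 1166.2 and 21.8 CPM in the libraries labelled Tet1-KO.

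The average Tet1-KO comparison was repeated with the Tet1-KO and Tet1-WT labels exchanged within stage and sex. Of 60 such groupings drawn with a fixed seed, the real one included, 1 gave as many genes, a share under the 0.05 set before. A grouping that mixes both labels adds their difference to the spread within groups, which lowers its count. The test therefore cannot exclude chance, nor tell Tet1 loss from another difference between the libraries, such as RNA of somatic cells. The real grouping gave 2446 genes, the highest of the others 2279 and the next 623.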
